A study of Mus musculus with 12 samples.

How the data were processed

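RNA was measured in 12 libraries of cDNA from mouse cells, with 2 libraries in each of 6 groups. The labels call the cells of 4 libraries BMDM (bone marrow-derived macrophages) and name a TREX knockout for them, with the numbers 1 to 4 in the names. These 4 libraries were treated with SSTC3, a compound known as an activator of the kinase CK1α, or with its solvent DMSO. The other 8 libraries are labelled MEF (mouse embryonic fibroblasts) and compare CK1α overexpression with its control, and CK1α knockdown by siRNA with its control. No label gives a dose, a time, the construct or the siRNA sequence.

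Reads were aligned with HISAT2 and assigned to genes of mm10 with featureCounts, per the submitters' processing notes, and the deposited files hold the resulting counts per gene, as whole numbers with no scaling. Tool versions, the strand setting and the gene annotation are not given in the sources used here. The files of the overexpression comparison list 55401 features and the other files 54532, of which 54100 are shared. The overexpression files have no counts for mitochondrially encoded genes, so that list was tested only in the other 2 comparisons. Gene symbols and positions come from GENCODE M21, whose build is mm10, and 260 and 123 features had no symbol there.

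From these counts, each comparison was tested on its own 4 libraries with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and scaling by TMM factors, with robust estimation and no block. Log2 fold changes are given with a standard error (SE) taken as their absolute value divided by the square root of F. For large changes from low counts this SE can be too small, as it can lie below the counting error. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Levels inside a comparison are CPM, counts scaled to a common library size, here with TMM factors, as mean ± SD with n = 2 libraries per group. Levels set side by side across cell sets are CPM of the library total. Genes tested numbered 14151 for SSTC3, 13958 for overexpression and 14832 for knockdown, with a common biological coefficient of variation of 0.0341, 0.0396 and 0.0431. Each fit had 2 residual degrees of freedom, and the spread was moderated across genes with prior degrees of freedom of 254.2, 51.2 and 59.5.

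In all, 34 gene lists were written before the data were examined, as were the tests of the comparisons, lists, differences and overlaps, the alternatives and the rule for naming genes. The tests of the closing section were chosen later, as stated there. Lists with 3 or more tested members were tested against all other genes with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a comparison. Lists can share members, so their results are not independent of each other. Each list test within a comparison was repeated with a correlation estimated from its 4 libraries. Differences between effects were tested as contrasts in a single edgeR fit of all 12 libraries, which also gave the estimated correlation for lists there. Overlaps of calls were tested with a two-sided Fisher exact test over genes tested in both comparisons, which share no library. Named genes are those of the casein kinase 1 family, a fixed panel of 20 genes, the 8 largest changes per direction at 4 CPM or more with separated groups and an established symbol, and up to 4 members per list with the smallest adjusted p-values. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

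Replicates were compared before averaging. The chi-square of each pair's counts over genes with a summed count of 20 or more was 2.29 to 3.61 per degree of freedom, so each pair differed by more than sampling noise and no library was counted as a copy. The numbers of the replicates showed no shared structure across groups and were not used as pairs. No label says that replicates came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

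The procedure was tested on simulated data with 200 changed genes per comparison, as many higher as lower. In the data, 53.6% (SSTC3), 13.3% (overexpression) and 54.7% (knockdown) of genes were called. With so many more genes changing, the simulated shares need not carry over to the data. For SSTC3, over 14151 genes, it recovered 73.1% of 1.5-fold, 73.1% of 2-fold and 98.5% of 4-fold changes, and 3% of its calls were unchanged genes. For overexpression, over 13958 genes, the recovered shares were 64.2%, 86.6% and 97%, and 8.8% of calls were unchanged genes, above the 5% that the threshold allows. For knockdown, over 14832 genes, they were 59.7%, 76.1% and 95.5%, and 12% of calls were unchanged genes, also above 5%.

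Alternatives were a minimum change of 2-fold, RLE factors, library totals, DESeq2 1.42.0, limma-voom, no filter, at least 1 CPM in 2 libraries, all 12 libraries in the fit, the replicate number as a block, and leaving out each library. Lists were also tested with fry. Library totals ran from 16063627 to 19427506 counts, and a gene at 0 in a group was bounded with a floor of 3 counts over the group, which covers counting error only. Python 3 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 made the summaries.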

Results

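Gene counts were obtained for 12 mouse RNA libraries in 6 groups of 2. Library totals ran from 16063627 to 19427506 counts, and 20266 to 22950 genes had at least 1 count. The series concerns the kinase CK1α, encoded by Csnk1a1, and its relation to cGAS-STING signalling, the pathway by which cytosolic DNA raises interferon. Its 3 comparisons are meant to change CK1α in different ways, by a compound (SSTC3), by overexpression and by knockdown.

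Csnk1a1 (ENSMUSG00000024576, mm10 chromosome 18, 61555274 to 61590061, plus strand) was read first as a check of the labels. In the knockdown libraries it had 171.5 and 169.2 CPM, against 325.0 and 354.1 CPM in their controls, a log2 fold change of −0.96 ± 0.05 (SE, n = 2 per group, adjusted p = 2.88e-27). The libraries labelled CK1a_OE had 229.3 and 244.4 CPM against 237.8 and 234.7 CPM in their controls, a log2 fold change of −0.01 ± 0.04 (adjusted p = 0.901), so no higher transcript level was measured there. A construct from another species or without the counted exons might be missed by these counts, which was not tested. The direction of the overexpression comparison rests on the label alone. SSTC3 libraries had 426.4 and 424.0 CPM against 413.2 and 430.0 CPM with DMSO, and the change of 0.07 ± 0.04 did not pass (adjusted p = 0.111).

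**Figure D1:**
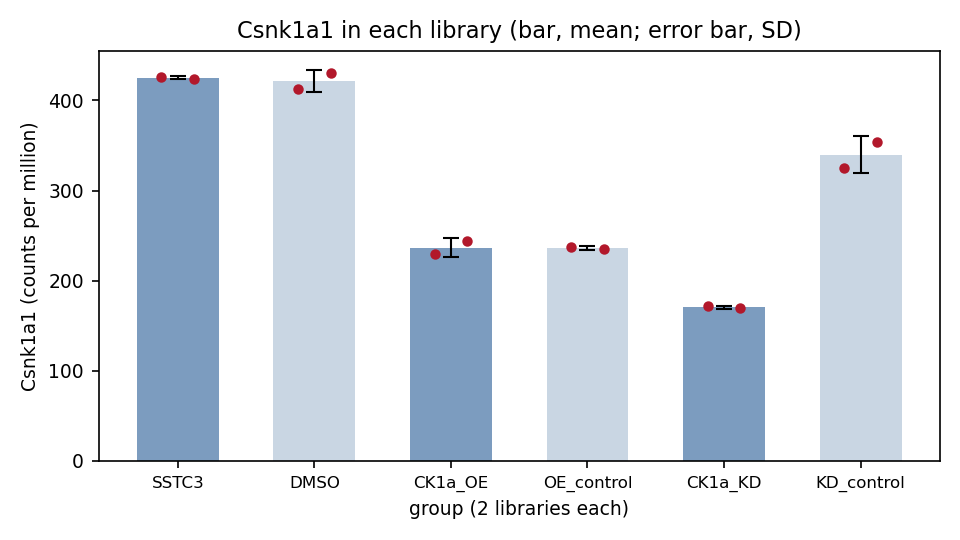
Csnk1a1 in CPM of the library total (y axis) for the 6 groups (x axis); points are the 2 libraries of each group, bars their mean and error bars the SD. The CK1a_KD libraries lie at 171.5 and 169.2 against 325.0 and 354.1 in KD_control, and the CK1a_OE libraries lie at the level of their controls.

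Trex1 (chromosome 9, 109057933 to 109059734) had 0 counts in all 12 libraries. Its exons lie within those of Atrip (chromosome 9, 109057933 to 109074124, same strand), and 100% of its exonic bases are shared, so the counts cannot check the knockout label. Atrip itself had 22.7 to 44.1 CPM, and Trex2 had at most 2 counts in any library.

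The 4 libraries labelled BMDM held few macrophage transcripts. The 21 macrophage markers summed to 10.4 to 13.2 CPM there, and 12 to 14 of them had 0 counts. The 14 fibroblast markers summed to 7304 to 8581 CPM in the same libraries, above the 2126 to 2610 CPM of the overexpression set and the 3246 to 3997 CPM of the knockdown set. Their median was 44.65 to 58.89, 17.88 to 23.54 and 10.27 to 13.38 CPM in the same order, so a few abundant markers carry these sums. Macrophage markers summed to 21.5 to 24.0 CPM in the overexpression set and to 272 to 329 CPM in the knockdown set, most of it from Cd68, with a mean of 295 ± 1.03 CPM in knockdown and 249 ± 4.26 CPM in control libraries (SD, n = 2). The 2 sets labelled MEF also differ from each other in Cdkn2a, Twist1 and Kdm5d, genes chosen after their values were seen. These had 0 counts in the knockdown set. Their group means in the overexpression set were 305 to 317, 31.0 to 35.7 and 19.1 to 23.5 CPM, in this order. Ddx3y and Eif2s3y, chosen likewise, had 58.4 to 65.7 and 34.6 to 34.7 CPM there and 0 counts in the knockdown set. They also had 0 counts with SSTC3 and DMSO, where Kdm5d had 19.3 and 20.9 CPM. Those files list as many features as the knockdown files, so for these 2 genes a difference of annotation cannot be told apart. Col3a1, a fibroblast collagen gene also chosen after its values were seen, had group means of 6.97 to 7.86 CPM in the knockdown set, 21.3 to 34.0 CPM in the overexpression set and 796 to 1016 CPM in the set labelled BMDM.

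**Figure D2:**
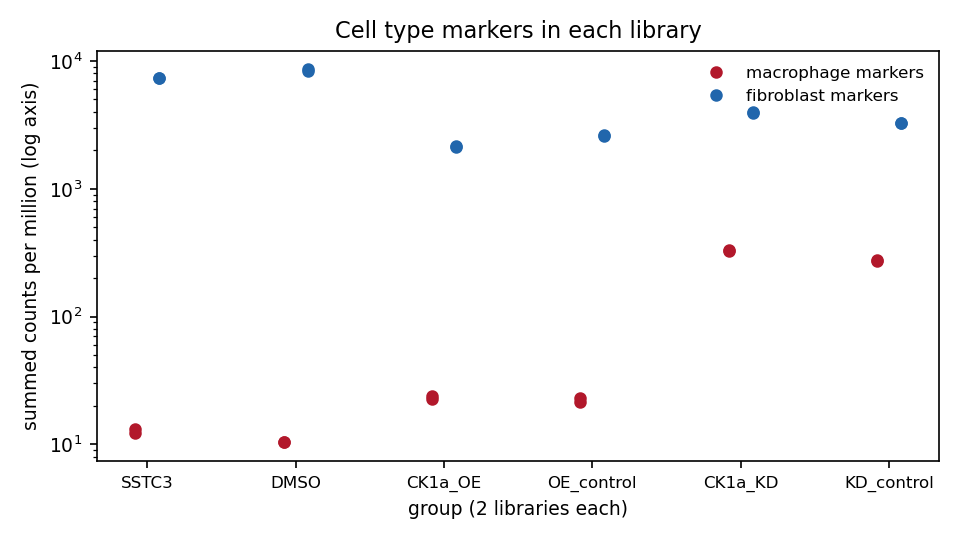
Summed CPM of the library total (y axis, log scale) of 21 macrophage markers and 14 fibroblast markers in each of the 2 libraries of the 6 groups (x axis). In the SSTC3 and DMSO libraries the macrophage markers sum to 10.4 to 13.2 and the fibroblast markers to 7304 to 8581.

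SSTC3 against DMSO asks what activation of CK1α does in the cells labelled BMDM. With SSTC3, the immediate early genes Fos and Egr1 rose the most: Fos was 336 ± 14.2 against 0.608 ± 0.0346 CPM and Egr1 was 2219 ± 22.3 against 4.96 ± 1.41 CPM (SD, n = 2 per group). The heat shock genes Hspa1b (2086 ± 0.950 against 26.0 ± 1.82 CPM) and Hspa1a (475 ± 5.02 against 1.19 ± 0.111 CPM) rose as well. They are near-identical copies, so the split between them is uncertain, and no list of heat shock genes was tested. Cxcl10, an interferon-inducible chemokine, was 511 ± 14.2 against 20.3 ± 1.81 CPM, and Ifit1, an interferon-stimulated gene, 94.8 ± 2.62 against 15.7 ± 0.288 CPM. Falling transcripts included Cxcl12, a stromal chemokine, at 61.9 ± 0.783 against 253 ± 1.31 CPM.

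Of 14151 genes tested, 7579 passed the threshold, 3830 higher and 3749 lower with SSTC3, a balance that turned to 3290 higher and 4419 lower with library totals as the scaling. A change of at least 2-fold was passed by 1505 genes, 1166 higher and 339 lower. The 8 largest rises were Fos (log2 fold change 9.09 ± 0.10, SE), Egr1 (8.80 ± 0.06), Egr2 (8.76 ± 0.30), Hspa1a (8.64 ± 0.09), Fosb (8.17 ± 0.09), Egr3 (7.73 ± 0.22), Wnt11 (6.49 ± 0.37) and Hspa1b (6.33 ± 0.05). Fos and Hspa1a started from few counts with DMSO, so their SE is too small. The 8 largest falls were Kcnj2 (−2.60 ± 0.25), Osr1 (−2.14 ± 0.19), Bmf (−2.08 ± 0.18), Efna4 (−2.08 ± 0.14), Cxcl12 (−2.03 ± 0.05), Igsf10 (−2.0 ± 0.12), Gas1 (−1.94 ± 0.06) and Maf (−1.85 ± 0.12). Dnajb1 and Hsph1, further heat shock genes chosen after their values were seen, had log2 fold changes of 4.35 ± 0.04 and 2.79 ± 0.04.

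All 25 immediate early genes tested rose with SSTC3, also when adjusted over the list alone, with a median log2 fold change of 4.08 (camera adjusted p = 5.79e-42; adjusted p = 0.078 with an estimated correlation). Of 40 interferon-stimulated genes, 31 rose, 2 fell and 7 did not pass, and adjusted over the list alone 32 rose and 2 fell. Their median was 1.84 (adjusted p = 1.07e-12; adjusted p = 0.078 with an estimated correlation), and members included Ifih1 (4.17 ± 0.12), Ifit1 (2.60 ± 0.08) and Isg15 (2.47 ± 0.09). Of the 18 interferon-inducible GTPases, 7 had enough counts to be tested. All 7 rose, and as many adjusted over the list alone, such as Gbp3 (2.56 ± 0.17) and Irgm1 (2.04 ± 0.15). Their list had an adjusted p = 3.04e-05, and adjusted p = 0.135 with an estimated correlation. Interferons and IRF3-driven chemokines had 6 of 7 higher, as adjusted over the list alone, among them Ccl5 (3.11 ± 0.19), with adjusted p = 7.45e-07 and adjusted p = 0.11 with an estimated correlation. Cgas (0.15 ± 0.07, adjusted p = 0.069), Tbk1 (0.00 ± 0.07, adjusted p = 0.999), Irf3 (0.12 ± 0.09, adjusted p = 0.274) and the STING gene Tmem173 (−0.19 ± 0.12, adjusted p = 0.183) did not pass. Ifnb1, Tnf and Il1b had too few counts to be tested.

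Inflammatory NF-κB genes had 22 of 28 higher and 1 lower, and 23 and 2 adjusted over the list alone, such as Ptgs2 (3.58 ± 0.09), Cxcl1 (2.68 ± 0.05) and Ccl2 (2.11 ± 0.05). The list passed with adjusted p = 9.32e-15, and adjusted p = 0.078 with an estimated correlation. For the integrated stress response 22 of 26 rose and 1 fell, 24 and 1 adjusted over the list alone, led by Atf3 (5.97 ± 0.07), Ppp1r15a (2.72 ± 0.06) and Ddit3 (2.35 ± 0.07). This list had adjusted p = 8.92e-18, and adjusted p = 0.078 with an estimated correlation. Unfolded protein response genes of the endoplasmic reticulum rose in 18 of 21 cases with none lower, and so did they adjusted over the list alone, including Dnajb9 (2.76 ± 0.12) and Hspa5 (1.90 ± 0.03). Their adjusted p = 5.48e-11 became adjusted p = 0.0878 with an estimated correlation. Among 33 p53 targets, 25 rose and 2 fell on either adjustment (over all genes or adjusted over the list alone), with Btg2 (4.08 ± 0.08), Cdkn1a (3.42 ± 0.05) and Mdm2 (2.31 ± 0.05) among them. Here the adjusted p = 2.98e-13 became adjusted p = 0.078 with an estimated correlation.

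Contractile and TGF-β or YAP-responsive genes had 13 of 17 higher and none lower, as adjusted over the list alone, for example Ccn1 (3.44 ± 0.04). Their adjusted p = 1.59e-10 became adjusted p = 0.0918 with an estimated correlation. Autophagy and lysosome genes had 29 of 41 higher and 3 lower, 32 and 3 adjusted over the list alone, with Sqstm1 at 0.73 ± 0.04, and the list had adjusted p = 6.1e-06, and adjusted p = 0.11 with an estimated correlation. MHC class I presentation had 10 of 17 higher, also adjusted over the list alone, such as Tap1 (2.14 ± 0.13) and H2-D1 (1.51 ± 0.06), and the list had adjusted p = 0.000349, and adjusted p = 0.147 with an estimated correlation. Members of the list of Hedgehog targets fell in 7 of 11 cases and rose in 2, as adjusted over the list alone, such as Gli2 (−1.50 ± 0.13) and Ptch1 (−0.76 ± 0.07). That list had adjusted p = 0.00113, and adjusted p = 0.266 with an estimated correlation. The lists of Wnt targets (higher, adjusted p = 0.045), clock genes (higher, adjusted p = 0.0299), alternative activation (higher, adjusted p = 0.0308) and fibroblast markers (lower, adjusted p = 0.0408) passed narrowly. In the same order they had adjusted p = 0.266, adjusted p = 0.266, adjusted p = 0.266 and adjusted p = 0.353 with an estimated correlation. None of the calls held without DMSO replicate 2, where the adjusted p was 0.0906, 0.0604, 0.0604 and 0.0826. The remaining 14 of 30 lists tested did not pass, mitochondrially encoded transcripts among them (adjusted p = 0.148), and in 3 of them the median, the mean and the test differed in sign.

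The overexpression comparison asks what more CK1α does in cells labelled MEF. Libraries labelled CK1a_OE differed from their controls by small amounts. The matrix genes Ecm1 and Thbs1 fell, Ecm1 to 901 ± 9.23 against 1178 ± 17.3 CPM and Thbs1 to 322 ± 4.46 against 440 ± 4.05 CPM (SD, n = 2 per group). Of the interferon-stimulated genes, Ifitm3 fell to 383 ± 9.03 against 472 ± 0.567 CPM and Lgals3bp to 44.7 ± 0.269 against 62.3 ± 1.42 CPM. Insig1, a regulator of sterol synthesis, rose to 33.4 ± 2.12 against 21.4 ± 0.813 CPM, and Cyp51, an enzyme of that pathway, to 125 ± 5.51 against 92.6 ± 4.32 CPM.

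Of 13958 genes tested, 1863 passed, 807 higher and 1056 lower (978 and 948 with library totals), and at least 2-fold changes were passed by 110 genes, 10 higher and 100 lower. The count was 519 with DESeq2, 1188 with all 12 libraries in the fit, 1065 without OE_control replicate 1 and 1220 without OE_control replicate 2. The largest rise was Dynlt1c (1.98 ± 0.17, SE), which has near-identical copies on the same chromosome and is therefore uncertain, followed by Zfp653 (1.00 ± 0.22). Further rises were Rragb (0.71 ± 0.24), Mertk (0.66 ± 0.19), Zfp184 (0.65 ± 0.22), Crlf2 (0.64 ± 0.19), Insig1 (0.64 ± 0.10) and Xpa (0.62 ± 0.16). Of these, Rragb (adjusted p = 0.224), Zfp184 (adjusted p = 0.458), Crlf2 (adjusted p = 0.153) and Xpa (adjusted p = 0.113) did not pass without OE_control replicate 2, and Mertk (adjusted p = 0.26) did not pass without OE_control replicate 1. The largest falls were Colec10 (−1.53 ± 0.23), Palm3 (−1.22 ± 0.22), Plekha7 (−1.19 ± 0.24), Col6a3 (−1.12 ± 0.25), Hist1h1c (−1.11 ± 0.23), Inpp5d (−1.11 ± 0.18), Atg9b (−1.10 ± 0.18) and Dchs2 (−1.09 ± 0.14). Without CK1a_OE replicate 1, Col6a3 did not pass (−0.78, adjusted p = 0.0594).

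Extracellular matrix genes fell in 18 of 26 cases with none higher, 19 adjusted over the list alone, such as Thbs2 (−0.55 ± 0.05), Thbs1 (−0.45 ± 0.03) and Col1a1 (−0.72 ± 0.07). Their median was −0.24 (adjusted p = 2.34e-24; adjusted p = 0.112 with an estimated correlation). Fibroblast markers fell in 5 of 10 cases, also adjusted over the list alone, with adjusted p = 8.23e-08, and adjusted p = 0.112 with an estimated correlation. Of 41 interferon-stimulated genes, 13 fell, 0 rose and 28 did not pass, and 22 fell adjusted over the list alone. The median was −0.28 (adjusted p = 3.89e-10; adjusted p = 0.112 with an estimated correlation). Members were Lgals3bp (−0.48 ± 0.07), Ifitm3 (−0.30 ± 0.03) and Bst2 (−0.31 ± 0.06). Isg15 fell by 0.38 ± 0.09 on the log2 scale (adjusted p = 0.00399), a call that ended without OE_control replicate 2 (−0.27, adjusted p = 0.148). Ifit1 (−0.25 ± 0.09, adjusted p = 0.0596), Irf7 (−0.38 ± 0.17, adjusted p = 0.124), Cxcl10 (−0.07 ± 0.04, adjusted p = 0.334) and Ccl5 (0.00 ± 0.13, adjusted p = 0.991) did not pass. Cgas (0.21 ± 0.07, adjusted p = 0.0255) and Tbk1 (0.19 ± 0.07, adjusted p = 0.0398) passed with all 4 libraries and did not pass when any 1 of them was left out, with adjusted p up to 0.18 for Cgas and 0.171 for Tbk1.

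Cholesterol synthesis genes rose in 10 of 24 cases and fell in 1, 15 and 1 adjusted over the list alone, with Msmo1 (0.50 ± 0.06) and Cyp51 (0.43 ± 0.05) among them. The list had adjusted p = 4.43e-10, and adjusted p = 0.112 with an estimated correlation. Integrated stress response genes rose in 15 of 26 cases and fell in 1, 16 and 2 adjusted over the list alone, such as Atf3 (0.42 ± 0.05) and Trib3 (0.42 ± 0.07), and the list had adjusted p = 1.36e-07, and adjusted p = 0.112 with an estimated correlation. Autophagy and lysosome genes had 13 of 41 higher, 16 adjusted over the list alone, with Sqstm1 at 0.22 ± 0.03, and the list had adjusted p = 3.08e-07, and adjusted p = 0.112 with an estimated correlation. For p53 targets 17 of 34 fell and 2 rose, 18 and 3 adjusted over the list alone, with Mdm2 (−0.16 ± 0.02) and Cdkn1a (−0.15 ± 0.03), and the list had adjusted p = 3.08e-07, and adjusted p = 0.112 with an estimated correlation. TGF-β and YAP-responsive genes had 8 of 19 lower and 1 higher, 8 and 2 adjusted over the list alone, including Acta2 (−0.45 ± 0.03), and the list had adjusted p = 1.37e-06, and adjusted p = 0.211 with an estimated correlation.

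Smaller lists also passed in the overexpression comparison. The GTPases (4 of 9 lower, as adjusted over the list alone) had adjusted p = 0.00608, and adjusted p = 0.25 with an estimated correlation, a call that ended without OE_control replicate 2 (adjusted p = 0.124). Dendritic cell markers were lower (adjusted p = 0.00258; adjusted p = 0.249 with an estimated correlation), on 3 tested genes with Fscn1 (−0.21 ± 0.03) the only member past the threshold and all 3 lower adjusted over the list alone. NF-κB genes were higher (7 of 27 rose, 8 adjusted over the list alone; adjusted p = 0.0176; adjusted p = 0.251 with an estimated correlation). Lower lists were Wnt targets (adjusted p = 0.00608; adjusted p = 0.251 with an estimated correlation) and Hedgehog targets (adjusted p = 0.0176; adjusted p = 0.291 with an estimated correlation). Interferons and chemokines (adjusted p = 0.0418; adjusted p = 0.268 with an estimated correlation), MHC class II (adjusted p = 0.0418; adjusted p = 0.314 with an estimated correlation) and muscle and neural markers (adjusted p = 0.0418; adjusted p = 0.268 with an estimated correlation) were lower too. Hypoxia and glycolysis genes passed as lower (adjusted p = 0.0224; adjusted p = 0.251 with an estimated correlation), with a median of −0.06 and a mean of 0.01 that differ in sign. Without OE_control replicate 2, 10 lists passed in place of 17, and the adjusted p was 0.0681 for Wnt targets, 0.0745 for Hedgehog targets, 0.0681 for interferons and chemokines, 0.16 for MHC class II, 0.0745 for muscle and neural markers and 0.0537 for hypoxia and glycolysis. The NF-κB list did not pass without OE_control replicate 1 (adjusted p = 0.141). The remaining 12 of 29 lists tested did not pass, immediate early genes among them (4 of 25 higher and 3 lower, 4 and 4 adjusted over the list alone; adjusted p = 0.516), and 3 of them had a median, mean and test that differed in sign.

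The knockdown comparison asks what less CK1α does in cells labelled MEF. With Csnk1a1 lower, the interferon-stimulated genes Mx1 and Ifit1 rose, as Mx1 was 213 ± 12.5 against 5.66 ± 0.728 CPM and Ifit1 2445 ± 16.8 against 903 ± 52.3 CPM (SD, n = 2 per group). Cgas, the sensor of cytosolic DNA, was itself higher, at 25.2 ± 2.53 against 4.71 ± 0.294 CPM. The interferon genes Ifnb1 and Ifna4 fell, Ifnb1 to 6.30 ± 0.757 against 13.4 ± 1.56 CPM and Ifna4, a member of a family of close copies, to 5.80 ± 0.167 against 52.1 ± 0.0465 CPM. The immediate early gene Egr1 fell to 84.1 ± 1.34 against 708 ± 8.16 CPM, and the cytokine gene Tnf to 1.24 ± 0.281 against 11.5 ± 0.190 CPM.

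Of 14832 genes tested, 8113 passed, 4196 higher and 3917 lower (3864 and 4226 with library totals), and a change of at least 2-fold was passed by 1797, 778 higher and 1019 lower. BC023105 was at least 133-fold higher, at 11.9 ± 0.154 CPM against 0 counts in both controls. Other large rises were Iigp1 (6.33 ± 0.09, SE), Ifi47 (5.97 ± 0.12), Mx1 (5.24 ± 0.09), Ifit1bl1 (4.95 ± 0.13), Gbp4 (4.84 ± 0.28), Tgtp1 (4.80 ± 0.18) and Igtp (4.68 ± 0.07). As with SSTC3, the SE of such large rises can be too small. Tgtp1 and Tgtp2 are near-identical, so the gene of origin is uncertain. The largest falls were Ccl20 (−3.82 ± 0.16), Dusp1 (−3.50 ± 0.07), Tcim (−3.36 ± 0.13), Kcne4 (−3.21 ± 0.13), Tnf (−3.20 ± 0.23), Ifna4 (−3.17 ± 0.11), Egr2 (−3.12 ± 0.13) and Fosb (−3.08 ± 0.10).

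Of 50 interferon-stimulated genes tested, 48 rose, 1 fell and 1 did not pass, with the same counts of 48 and 1 adjusted over the list alone. Their median was 1.69 (adjusted p = 5.93e-120; adjusted p = 0.0532 with an estimated correlation), with Parp14 (3.78 ± 0.06), Dtx3l (3.46 ± 0.06), Ifit2 (2.27 ± 0.05), Irf7 (2.35 ± 0.07) and Isg15 (1.15 ± 0.04) among them. The interferon-inducible GTPases rose in 17 of 17 cases, also adjusted over the list alone, with a median of 3.32 (adjusted p = 1.38e-62; adjusted p = 0.0532 with an estimated correlation). MHC class I presentation had 14 of 18 higher and 1 lower, also adjusted over the list alone, such as Psmb10 (2.53 ± 0.11), Tap1 (1.95 ± 0.05) and Tapbp (1.42 ± 0.04). That list had adjusted p = 6.04e-14, and adjusted p = 0.106 with an estimated correlation. Nucleic acid sensing components had 13 of 24 higher and 7 lower, also adjusted over the list alone, with adjusted p = 5.91e-05, and adjusted p = 0.106 with an estimated correlation. Within the pathway, Cgas (2.41 ± 0.14) and Tbk1 (0.84 ± 0.09) rose, and Tmem173 (−0.46 ± 0.11) and Irf3 (−0.46 ± 0.09) fell. Interferons and IRF3-driven chemokines were split, 7 of 12 higher and 4 lower, as adjusted over the list alone, with adjusted p = 1.5e-08, and adjusted p = 0.1 with an estimated correlation. Ccl5 (1.05 ± 0.04) and Cxcl10 (0.88 ± 0.04) rose in this list, and Ifnb1 (−1.10 ± 0.16) fell.

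Immediate early genes fell in 22 of 24 cases and rose in 1, 23 and 1 adjusted over the list alone, with Dusp1, Egr1 (−3.08 ± 0.05) and Jun (−2.04 ± 0.05) among them. Their median was −1.27 (adjusted p = 1.92e-44; adjusted p = 0.0532 with an estimated correlation). NF-κB genes fell in 19 of 29 cases and rose in 5, also adjusted over the list alone, with falls of Cxcl1 (−2.42 ± 0.05) and Il6 (−2.02 ± 0.07) and rises of Nfkb1 (1.62 ± 0.05) and Csf1 (1.16 ± 0.04). The list passed as lower with adjusted p = 2.19e-13, and adjusted p = 0.1 with an estimated correlation. Integrated stress response genes had 17 of 25 lower and 4 higher, also adjusted over the list alone, such as Ppp1r15a (−2.81 ± 0.04) and Ddit3 (−1.89 ± 0.06), and the list had adjusted p = 2.5e-10, and adjusted p = 0.1 with an estimated correlation. Unfolded protein response genes had 18 of 21 lower and 1 higher, also adjusted over the list alone, including Herpud1 (−2.70 ± 0.05), and the list had adjusted p = 3.67e-10, and adjusted p = 0.117 with an estimated correlation. Hspa5, a member chosen after its values were seen, had a mean of 13670 CPM after knockdown and 20600 CPM in the controls. Its mean was 836 CPM in the overexpression controls and 591 CPM with DMSO, so for this gene the fall began from a high level. Clock genes fell in 12 of 16 cases, also adjusted over the list alone, with Per1 at −2.01 ± 0.07, and the list had adjusted p = 1.43e-05, and adjusted p = 0.106 with an estimated correlation. Autophagy and lysosome genes had 21 of 41 lower and 4 higher, 21 and 5 adjusted over the list alone, with adjusted p = 0.00117, and adjusted p = 0.117 with an estimated correlation.

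Metabolic and proliferative lists were higher after knockdown. Cholesterol synthesis genes rose in 19 of 22 cases and fell in 1, also adjusted over the list alone, with Fdft1 (1.37 ± 0.07), and the list had adjusted p = 2.39e-08, and adjusted p = 0.106 with an estimated correlation. Hypoxia and glycolysis genes had 23 of 29 higher and 4 lower, also adjusted over the list alone, such as Pfkl (1.15 ± 0.05), and the list had adjusted p = 7.78e-08, and adjusted p = 0.1 with an estimated correlation. NRF2 targets had 17 of 23 higher and 1 lower, also adjusted over the list alone, such as Gsr (1.11 ± 0.07), and the list had adjusted p = 6.33e-08, and adjusted p = 0.1 with an estimated correlation. Cell cycle genes had 25 of 36 higher and 2 lower, 27 and 2 adjusted over the list alone, such as Ccne1 (1.81 ± 0.09), and the list had adjusted p = 4.17e-06, and adjusted p = 0.106 with an estimated correlation. The p53 targets went both ways, 11 of 32 higher and 12 lower, 11 and 13 adjusted over the list alone, with Cdkn1a (−0.91 ± 0.05) and Mdm2 (−0.46 ± 0.06) lower. Their list had adjusted p = 0.0474, and adjusted p = 0.245 with an estimated correlation, and did not pass without CK1a_KD replicate 1 (adjusted p = 0.43) or CK1a_KD replicate 2 (adjusted p = 0.26). The remaining 16 of 32 lists tested did not pass, mitochondrially encoded transcripts among them (adjusted p = 0.915), and in 10 of them the median, the mean and the test differed in sign. Among the other casein kinase 1 genes, Csnk1d was higher after knockdown (0.52 ± 0.05) and Csnk1e lower (−0.24 ± 0.07).

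**Figure D3:**
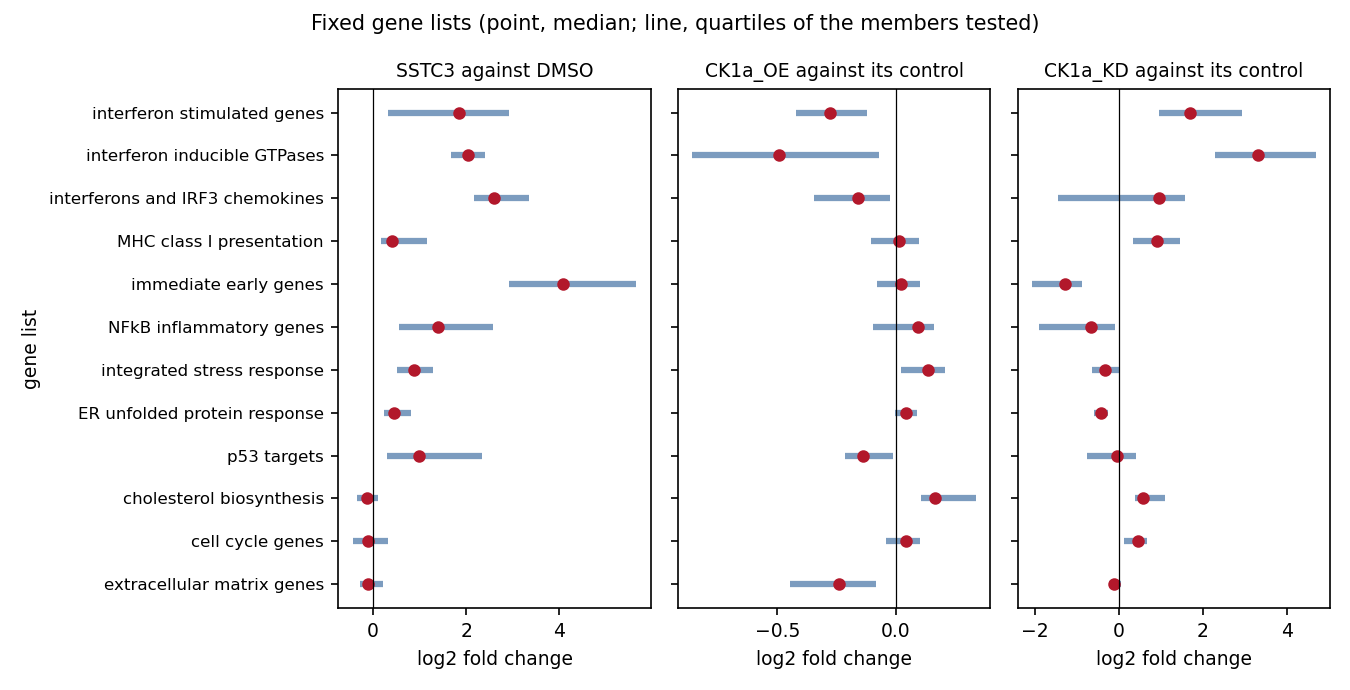
Log2 fold change (x axis, its own scale in each panel) of 12 fixed gene lists (y axis) in the 3 comparisons; points are medians and lines run from the first to the third quartile of the members tested. The median of the interferon-stimulated genes is 1.84 with SSTC3, −0.28 in the CK1a_OE libraries and 1.69 after knockdown, and that of the immediate early genes is 4.08, 0.02 and −1.27.

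The 3 comparisons were then set against each other, to ask whether they move the same genes. The difference between 2 effects passed for 6005 of 17105 genes for knockdown minus overexpression (3137 positive, 2868 negative). It passed for 5600 genes for SSTC3 minus overexpression (2941 positive, 2659 negative) and for 7707 genes for SSTC3 minus knockdown (4020 positive, 3687 negative). Each of these differences also holds the difference between 2 cell sets. For lists, the correlation was estimated here from all 12 libraries, so these values are not comparable with those estimated from 4 libraries. Interferon-stimulated genes were higher in the knockdown effect than in the overexpression effect (adjusted p = 1.22e-28; adjusted p = 0.000527 with an estimated correlation), for example Isg15 by 1.49 ± 0.08 and Irf7 by 2.70 ± 0.16. They were also higher in the SSTC3 effect than in the overexpression effect (adjusted p = 2.36e-16; adjusted p = 0.00115 with an estimated correlation). Between SSTC3 and knockdown the difference of this list did not pass (adjusted p = 0.717), although single members differed, such as Cxcl10 by 3.81 ± 0.06 and Isg15 by 1.35 ± 0.08. Immediate early genes (adjusted p = 7.45e-40; adjusted p = 0.0012 with an estimated correlation), NF-κB genes (adjusted p = 9.62e-14; adjusted p = 0.0012 with an estimated correlation) and the integrated stress response (adjusted p = 4.19e-17; adjusted p = 0.0012 with an estimated correlation) were higher in the SSTC3 effect than in the knockdown effect. Csnk1a1 itself differed by −0.98 ± 0.06 between knockdown and overexpression (adjusted p = 2.81e-26). Nearly all of this is the knockdown effect, as in the same fit Csnk1a1 changed by −0.998 after knockdown and by −0.014 with overexpression.

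SSTC3 and knockdown shared more calls in opposite directions than expected if the 2 sets of calls were independent. The expected numbers were not matched on expression level and genes do not vary independently, so the Fisher p-values here are descriptive. Among 12431 genes tested in both, 1220 were higher with SSTC3 and lower after knockdown against 901.7 expected (odds ratio 1.87, Fisher exact p = 5.2e-46), and 1380 were lower and higher against 1071.5 expected (odds ratio 1.75, Fisher exact p = 1.1e-39). Calls higher in both numbered 1036 against 1068.3 expected (Fisher exact p = 0.17). With at least 2-fold changes, 171 genes were higher with SSTC3 and lower after knockdown against 37.9 expected (odds ratio 7.41, Fisher exact p = 7.5e-70). At that limit genes higher in both also exceeded the expected number, 67 against 40.3 (odds ratio 1.81, Fisher exact p = 3.5e-05). Across all 12431 genes the 2 log2 fold changes had a Pearson r of −0.176 and a Spearman rho of −0.137, where genes are not independent replicates. Of the interferon-stimulated genes, 35 of 39 had the same sign in both comparisons, while the sizes of their changes had an r of −0.071 and a rho of −0.117 across genes. SSTC3 and overexpression shared 351 genes higher in both against 218.6 expected (odds ratio 2.2, Fisher exact p = 3.2e-25), and 347 higher with SSTC3 and lower in the CK1a_OE libraries against 264.6 expected (odds ratio 1.54, Fisher exact p = 1.7e-09). Genes lower in both numbered 308 against 271.0 expected (Fisher exact p = 0.0065), those lower with SSTC3 and higher in the CK1a_OE libraries 204 against 223.9 expected (Fisher exact p = 0.11), and r was −0.039 over 12662 genes. Overexpression and knockdown had r = 0.01 over 12339 genes, and the 4 combinations of directions each exceeded the expected number, with odds ratios from 1.22 to 1.41.

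Control libraries of the 3 cell sets had different levels of interferon-stimulated genes. The median CPM over the 53 members of the list was 35.0 and 36.7 in the 2 knockdown controls, 10.3 and 8.72 in the overexpression controls and 3.69 and 2.85 in the DMSO libraries, a comparison between cells that no test of the design covers. The DMSO libraries also carry the TREX knockout label, so genotype cannot be told apart from cell set here. The knockdown controls also held interferon transcripts, with Ifna4 at 52.6 and 52.8 CPM and Ifnb1 at 12.4 and 14.7 CPM, so they are not taken as untreated cells.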

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

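All alternatives were chosen before the data were examined, and none was added later. The next counts cover the genes other than Csnk1a1 that the naming rule takes, reported here or not. Of their values under the alternatives, 4441 kept direction and side of the threshold, 175 lost the threshold, 4 gained it and 26 changed sign. For lists these numbers are 694, 81, 20 and 24. Calls fell to 1505 (SSTC3), 110 (overexpression) and 1797 (knockdown) when a 2-fold change was required, which is the stricter test itself. Genes called in both comparisons at that limit numbered 79 in the same and 197 in opposite directions for SSTC3 and knockdown, 7 and 8 for SSTC3 and overexpression, and 5 and 11 for overexpression and knockdown. Overexpression calls were 519 with DESeq2, 1188 with all 12 libraries in the fit and 1065 to 1478 when a library was left out, where the lone library left in a group is assumed to vary like the others. List calls fell to 0 in each of the 3 comparisons with an estimated correlation, which 4 libraries estimate poorly, and ranged from 10 to 16 for overexpression when a library was left out. The replicate block gave 7303, 1768 and 8066 calls.

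Values that changed sign had not passed the threshold, and the cause was not tested. In the overexpression comparison Csnk1a1 was 0.003 with library totals and −0.054 to 0.034 with a library left out; the same ranges were −0.068 to 0.072 for Ccl5, −0.004 to 0.071 for Csnk1d, −0.065 to 0.029 for Csnk1e, −0.076 to 0.099 for Csnk1g2, −0.335 to 0.148 for Hdc, −0.115 to 0.385 for Il6 and −0.033 to 0.001 for Tmem173, and Ccl5 was 0.0 at 1 CPM in 2 libraries and −0.001 with all libraries. With SSTC3, Csnk1e was −0.039 with library totals, −0.005 with DESeq2, −0.003 with no filter and −0.052 to 0.073 with a library left out. Tbk1 was −0.005 with RLE factors, −0.055 with library totals, −0.02 with DESeq2, −0.019 with no filter, −0.008 with all libraries and −0.021 to 0.016 with a library left out. List tests that changed sign had these adjusted p-values. For SSTC3, hypoxia and glycolysis had 0.0936 with fry, 0.807 with the block and 0.5 to 0.832 with a library left out, and dendritic markers 0.95 and 0.574 to 0.951. For overexpression, macrophage markers had 0.691 with all libraries and NRF2 targets 0.922 with library totals; with a library left out the ranges were 0.687 to 0.966 for NRF2 targets, 0.339 to 0.886 for immediate early genes, 0.722 to 0.872 for MHC class I and 0.257 to 0.795 for nucleic acid sensing. For knockdown, alternative activation had 0.656 and Wnt targets 0.906 with all libraries; with a library left out the ranges were 0.736 to 0.957 for alternative activation, 0.781 to 0.957 for Wnt targets, 0.853 to 0.957 for casein kinase 1 genes and for muscle and neural markers, 0.924 to 0.986 for neutrophil markers and 0.781 to 0.996 for TGF-β and YAP targets.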

Other observations

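The tests on abundant macrophage transcripts, fibroblast markers, library totals, Csnk1a1 and chromosome 15 were chosen after the results they measure were seen, and those on exon overlap and matched random lists after the patterns were seen but before their own values.

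The libraries labelled BMDM held few macrophage transcripts. Loss of reads to overlapping genes is argued against, since only 1 of the 21 macrophage markers (Itgam, 68.7%) has most of its exonic bases in exons of another gene. A mixture of macrophages and fibroblasts is argued against as well, since the highest of 8 abundant macrophage transcripts, among them Lyz2, Ctss and Csf1r, reached 0.589 CPM in these 4 libraries. Cells of a fibroblast kind in place of macrophages would account for at least 11 of 14 fibroblast markers lying above 1 CPM in each library, against 9 to 10 in the libraries labelled MEF, so a cell label that differs from the cells sequenced may be the explanation.

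Interferon-stimulated genes were higher in the SSTC3 and in the knockdown libraries, although the compound is known as an activator. With library totals as the scaling, the lower of the 2 medians was 1.66. TMM factors ran from 0.9805 to 1.0205 (SSTC3) and from 0.987 to 1.0149 (knockdown). Factors so near 1 could hardly move the medians, so this check cannot decide on scaling. A general rise of low-count genes is argued against. The median lay above 100% of 10000 random lists matched on mean expression in either comparison. Exchanged labels in the knockdown comparison are argued against by Csnk1a1 at −0.96. For SSTC3 and DMSO exchanged labels cannot be told apart from a true rise, since no transcript marks the compound and Csnk1a1 moved by 0.068. Open and untested are a response to transfection or to compound stress and a loss of CK1α activity shared by the treatments. A shared cause thus remains a hypothesis that may fail. Other lists went both ways. Immediate early genes had medians of 4.08 with SSTC3 and −1.27 after knockdown, while MHC class I presentation was higher in both. Across all genes tested in both comparisons r was −0.176, so a shared cause would not account for the whole of both responses.

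Genes around 52 Mb of chromosome 15 had a higher level in the 4 libraries of the overexpression comparison than in the other 8, such as Eif3h (mean 3343 against 288 CPM) and Rad21 (3569 against 311 CPM), genes chosen after their values were seen. The 5 other expressed genes within 2 Mb had a median log2 ratio of 3.4, so extra copies of the region in these cells may be the source. Scattered annotation differences are argued against, as 4 of these 5 genes were at least 4-fold higher against 451 of 11217 elsewhere (Fisher exact p = 1.3e-05). The region is raised in CK1a_OE and control libraries alike, and no DNA was measured.

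Gm23935, a feature in no list and chosen after its values were seen, had 2219 and 2456 CPM with SSTC3 against 4247 and 5486 CPM with DMSO, a log2 fold change of −1.003 ± 0.191 (edgeR adjusted p = 0.0493).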
